A study of Mus musculus with 5 samples.

How the data were processed

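Gene expression was measured on 5 single-colour oligonucleotide arrays, with 1 array for each of days 2, 6, 9, 12 and 15 of culture. Per the labels' protocols, chondrocytes were released from the rib cages of FVB mouse embryos at gestational day 18.5 by collagenase and trypsin digestion, passed through a strainer and plated on gelatin-coated dishes. The medium held ascorbic acid and beta-glycerophosphate, total RNA was extracted with Trizol, and biotin-labelled target was made with a one-cycle labelling kit.

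The deposited values were probe-set signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, with no version given. The table held 45101 probe sets on all 5 arrays. The mean of each array after trimming 2% at both ends was 500, so the arrays had been scaled to a common mean before deposit. Such scaling compares each probe set with the average of its own array, and a shift shared by most transcripts would not be seen. Detection calls and scanner files were not used here.

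Probe sets were named through the platform annotation given with the table. Of the 45101 probe sets, 64 were control probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. Symbols were updated through an NCBI RefSeq gene table of assembly GRCm38.p6, used for names only. This placed 34741 probe sets under a current symbol, and 204 kept the older one. No gene was named from a probe set with several symbols.

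Intensities below the 40th percentile of all values, 73.1, were set to that floor, and log2 was taken. A gene was represented by its brightest probe set, the one with the highest mean intensity over the 5 arrays. Genes were kept when that mean reached 105.93, the median over all probe sets, which left 11075 of 18193 genes. A gene at the floor on one of the days compared gives only a bound, written as "at least". Fold differences are ratios of floored intensities and understate the difference of dim genes.

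Differences between days were counted at a threshold of 2-fold, with no test, because 1 array per day leaves no replicate error and no p-value for a difference between 2 days. The number of arrays limits the precision of every value. The labels do not say whether the 5 arrays came from dishes of a common cell isolate, so the spread about a trend may be partly technical. The only test was a linear trend of log2 intensity on day, fitted to the 5 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 residual degrees of freedom, 2.83 prior degrees of freedom, Benjamini-Hochberg adjustment over 11075 genes, adjusted p threshold 0.05). Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.

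The 27 gene lists, 17 for biology and 10 for other cell types a rib cage isolate could hold, were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. They hold 424 distinct genes, of which 295 were measured, 95 lay below the intensity filter and 34 had no probe set of their own in the annotation used here. The median log2 difference of each list was placed among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these arrays. Genes named in the text were the 12 highest and 12 lowest at day 15 against day 2 among genes above the floor on both days whose days 9, 12 and 15 lay on one side of day 2. The 5 largest bounds in each direction were added. From each list came the 4 members with the largest difference and up to 20 best known genes. The 6 highest peaks and 6 deepest troughs on a middle day, the 4 largest differences in each direction at each step between consecutive days, and the 5 lowest trend p-values in each direction completed the rule. Genes without an official symbol were counted and not named.

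The trend fit was tested on simulated data for the same 11075 genes, with 200 genes given known slopes. It recovered 0, 18, 45 and 47 of 50 genes whose total change from day 2 to day 15 was 1, 2, 3 and 4 on the log2 scale, and 8 of its 118 calls were false. The simulated changes were straight lines with noise unrelated to the slope, so these rates do not carry over to curved courses. Ibsp, whose log2 difference was 8.04 but whose course was not straight, had a limma adjusted p of 0.0651. The list percentile was tested with 200 lists of 15 genes drawn at random from the day 15 against day 2 differences, each placed among 500 random lists. Of these 200, 9 fell outside the central 95% without a shift, and 191 exceeded the 97.5th percentile after a shift of 1. Members of a fixed list may vary together, unlike genes drawn at random, so these rates do not carry over to the fixed lists.

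Alternatives were quantile normalization, centring each array on its median, floors at the 20th and 60th percentiles, a pseudocount of 73.1 in place of the floor, the mean over all probe sets of a gene, no filter, a filter at the 70th percentile, days 12 and 15 pooled against days 2 and 6, and, for the trend, log2 or rank of the day, an intensity trend in the prior and leaving out each array in turn. After the data were examined, 5 were added: day 15 against day 6, day 15 against day 9, day 12 against day 2, a step between days 6 and 9 in the trend, and a trend over days 9 to 15.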

Results

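Transcript levels were followed in primary mouse rib chondrocytes, the cells that make cartilage, over 15 days in a culture medium with ascorbic acid and beta-glycerophosphate, additives in common use for matrix formation and mineralisation in vitro. There were 5 arrays, 1 each for days 2, 6, 9, 12 and 15. The question set by the design was how expression differed with time in culture. Median intensity was 117, 118, 106, 108 and 107 on the 5 arrays in order of day, and 61.3%, 61.9%, 58.8%, 58.8% and 59.1% of probe sets lay at or above the floor of 73.1. The 3'-to-5' ratio of the Actb control probe sets, a measure of RNA integrity, ranged from 1.17 at day 2 to 1.27 at day 9. There was no second array on any day, so no difference between 2 days has a replicate check. The spread between probe sets was used as a guide to the error of a probe set. Probe sets of a gene are read on the same 2 arrays, so variation between arrays, labelling or dishes is not in that spread. Among 5158 genes with 2 probe sets, the SD of a log2 difference between day 15 and day 2 from 1 probe set was 0.55. Where the brightest probe set differed at least 2-fold, the other had the same direction in 89.3% of 1289 genes and also reached 2-fold in 57.3%. Of 45 genes with several probe sets that are named for a difference of at least 2-fold between days 2 and 15, 9 had another probe set under 2-fold: Ptn, Fabp4, Sox6, Wwp2, Cenpa, Idh3a, Ddit3, Nfatc1 and Acta2.

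Cells at day 15 had far more transcript for type I and type III collagen chains, bone sialoprotein and adiponectin than cells at day 2, and less for the cartilage proteoglycan aggrecan and for the peptidases Klk10 and Klk8. The largest measured difference was in Ibsp, bone sialoprotein, with an intensity of 133 at day 2 and 35026 at day 15, 264-fold higher (103-fold by another probe set). Ptn, a heparin-binding growth factor, was 125-fold higher by its brightest probe set and level by another (log2 difference -0.02), the small leucine-rich proteoglycan Aspn 123-fold higher, and the type I collagen chains Col1a1 and Col1a2 116-fold and 80.4-fold higher (12.5-fold and 2.89-fold by another probe set of each). Col3a1, the type III collagen chain, was 85.5-fold higher, the fatty acid binding protein gene Fabp4 93.6-fold higher (1.49-fold by another probe set), and Ppp1r3c, a regulator of glycogen synthesis, 79.8-fold higher. Adipoq, Tnmd, Cxcl12 and Hp, which encode adiponectin, tenomodulin, a chemokine and haptoglobin, were 74.7-fold, 69.2-fold, 65.5-fold and 64.8-fold higher. Genes at the floor on day 2 gave bounds of at least 123-fold for Ndufa4l2, at least 87.9-fold for Igfbp2, at least 82.3-fold for Selenop, at least 67.6-fold for Mfap5 (19.2-fold by another probe set) and at least 64.7-fold for Il1rn. By another probe set of each, Aspn was 63.3-fold, Ppp1r3c 31.3-fold, Il1rn 29.85-fold and Cxcl12 23.6-fold higher, and Col3a1 98.2-fold higher.

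The genes lowest at day 15 relative to day 2 were led by the kallikrein-related peptidases Klk10, 50.9-fold lower, and Klk8, 20.1-fold lower. Krt18, a keratin of simple epithelia, was 19.9-fold lower, with 2052 at day 2 and 103 at day 15. Fabp7, Cpm, Ncmap, the transcription factor Sim2 and Meltf were between 12.1-fold and 14.6-fold lower. Integrin alpha 6 (Itga6), the growth factor Hbegf, the procollagen C-proteinase enhancer Pcolce2 and Ndufaf4 were between 10.1-fold and 10.9-fold lower. Phlda2, the transcription factors Twist2 and Sox11, the desmosomal gene Pkp2 and Aldh3a1 were at the floor on day 15, which put them at least 38.7-fold, 22.7-fold, 17.9-fold, 14.7-fold and 12.4-fold lower (Sox11 2.65-fold by another probe set).

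Over all 11075 genes, 1798 were at least 2-fold higher and 1283 at least 2-fold lower at day 15 than at day 2, together 27.8% of genes, and 578 and 198 of them differed at least 4-fold. Pearson's r across genes between the 2 arrays was 0.822, where genes are not independent replicates. The counts depended on the genes and days compared: a filter at the 70th percentile left 1159 and 783, and days 12 and 15 pooled against days 2 and 6 gave 1091 and 622. Day 15 against day 6 gave 932 and 682, and against day 9 554 and 449.

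**Figure D1:**
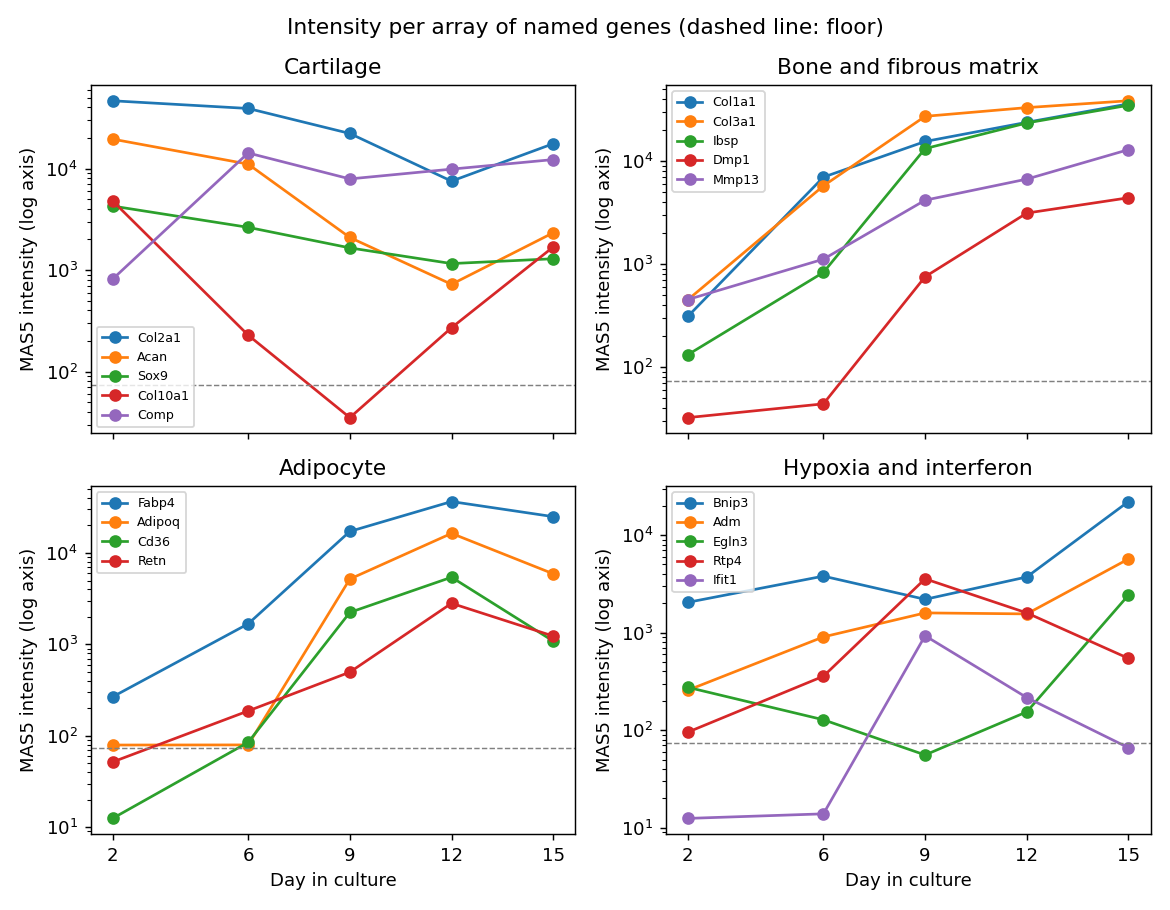
MAS5 intensity (log axis) against day in culture for named genes, 1 point per array, with the floor of 73.1 as a dashed line. Ibsp went from 133 at day 2 to 35026 at day 15, Acan from 19492 to 2328 with 723 at day 12, Adipoq was highest at day 12 with 16395, and Rtp4 at day 9 with 3563.

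Cartilage matrix genes were mostly lower at day 15. Of 19 measured members of that list, 12 were at least 2-fold lower, 4 at least 2-fold higher and 3 neither. Acan, the core protein of the main cartilage proteoglycan, had intensities of 19492, 11052, 2092, 723 and 2328 in order of day, 8.37-fold lower at day 15 than at day 2. Col2a1, the type II collagen gene, had 46505 at day 2, 7510 at day 12 and 17566 at day 15, 2.65-fold lower at the end. The 4 higher members were Comp at 15.1-fold, the lubricin gene Prg4 at least 9.03-fold, Fmod at 7.13-fold and Matn1 at 3.50-fold, and Comp and Fmod are also made by tendon and fibrous tissue. The list median was -1.41 on the log2 scale, below all 10000 random lists. Against day 2 it was 0.38 at day 6, -0.24 at day 9 and -1.40 at day 12, so the list did not fall steadily from day 2. From day 12 to day 15 the median was 0.28, with 12 of 19 members higher. Adjusted over the list alone, 8 members had a falling and 1 a rising linear trend, and adjusted over all genes tested 0 did, against 12 members at an unadjusted p under 0.05 by limma.

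Regulators of the chondrocyte state were lower or little different. Of 10 measured members, 5 were at least 2-fold lower and 0 at least 2-fold higher. Sox9, the transcription factor that drives cartilage gene expression, was 3.31-fold lower at day 15, with 4269 at day 2 and 1291 at day 15. Its partner Sox6 was 3.19-fold lower, the growth factor receptor gene Fgfr3 4.16-fold lower and the ubiquitin ligase gene Wwp2 2.14-fold lower. The list median was -0.96, at percentile 0.26 of the random lists, and -0.50 with days pooled, -0.31 against day 6 and -0.12 against day 9. Adjusted over the list alone, 3 members had a falling trend, and 0 over all genes tested, against 5 at an unadjusted p under 0.05 by limma.

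Genes of hypertrophic cartilage, the mature zone that precedes bone, split. The list held 14 genes, of which 12 had a probe set of their own, and 1 of these 12 lay below the intensity filter. Of 11 measured members, which leave out Ihh, Runx2 and Spp1, 7 were at least 2-fold higher at day 15 and 2 at least 2-fold lower. Mmp13, collagenase 3, was 28.5-fold higher, Panx3, a channel protein gene, 13.3-fold higher (2.18-fold by another probe set), and Alpl, the alkaline phosphatase of mineralising cells, had 126 at day 2 and 1640 at day 15. Col10a1, the type X collagen gene that marks hypertrophic chondrocytes, went the other way, with 4800 at day 2, 228 at day 6, 35.1 at day 9, 270 at day 12 and 1686 at day 15, which left it 2.85-fold lower than at day 2. The second lower member was Bmp6, at least 3.91-fold lower, a gene chosen for mention after its values were seen. The list median was 2.33, above all 10000 random lists, and 6 members had a rising and 1 a falling trend adjusted over the list alone, of which Mmp13 also passed over all genes tested. Most of the higher members belong to other lists too: Ibsp and Alpl to the osteoblast list and Mmp13 to the protease list. Pth1r is also in the hedgehog list and Vegfa in the hypoxia list, so the median is not independent of those lists. From day 9 to day 15 the median was 1.36.

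Osteoblast and mineralisation genes were higher at day 15 in 11 of 13 measured members and lower by 2-fold in 0. The list held 23 genes, of which 15 had a probe set of their own, and Runx2, Spp1 and Bglap were among those not measured. Besides Ibsp, Col1a1 and Col1a2, Dmp1, a matrix protein gene of mineralising osteoblasts and osteocytes, was at least 60.6-fold higher, with 32.6 at day 2 and 4432 at day 15. Sp7, which encodes the osteoblast transcription factor osterix, was 4.86-fold higher. The list median was 3.49, above all 10000 random lists, and the medians against day 2 were 0.61 at day 6, 2.51 at day 9 and 2.97 at day 12. All 11 of these members had a rising trend adjusted over the list alone and 0 over all genes tested. From day 9 to day 15 the median was 0.98.

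Fibroblast and dedifferentiation genes were higher in 14 of 21 measured members and lower in 1. Lum, a small proteoglycan gene of fibrous tissue, was 17.6-fold higher beside Col1a1, Col1a2 and Col3a1. Fn1, fibronectin, had 36924 at day 2 and 33831 at day 15 by its brightest probe set, but was 3.13-fold higher at day 15 by the other. The list median was 2.17, above all 10000 random lists, 1.40 with the floor at the 60th percentile, 1.29 with days pooled, 0.85 against day 6 and 0.50 against day 9, and 11 members had a rising trend adjusted over the list alone and 0 over all genes tested. Collagens of this list are shared with the osteoblast list, so the lists are not independent. Among matrix proteases and their inhibitors, 8 of 14 were at least 2-fold higher and 0 lower, with a median of 1.52 above all random lists, or 0.92 with that floor, 0.76 against day 6 and 0.65 against day 9. Adamts5, an aggrecan-cleaving protease, was 7.19-fold higher (23.9-fold by another probe set), the collagen-degrading cathepsin gene Ctsk 5.14-fold higher and the serine protease gene Htra1 4.26-fold higher. All 8 had a rising trend adjusted over the list alone, and Mmp13 over all genes tested.

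Cell cycle genes were lower at day 15, with 13 of 29 measured members at least 2-fold lower and 0 at least 2-fold higher. The DNA replication gene Mcm2 was 3.43-fold lower, the ribonucleotide reductase gene Rrm2 3.18-fold lower, the centromere gene Cenpa 2.78-fold lower and the mitotic kinase gene Plk1 2.76-fold lower. Mki67 and Top2a, both used to score proliferation, were 1.62-fold and 1.72-fold lower, under the 2-fold threshold, and Top2a 1.09-fold higher by another probe set. The list median was -0.78, below all 10000 random lists. It was -0.53 at day 6, -1.21 at day 9 and -1.13 at day 12 against day 2, and from day 9 to day 15 it was 0.20, the opposite sign. No member had a linear trend adjusted over the list alone (0 by limma, with 14 at an unadjusted p under 0.05).

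**Figure D2:**
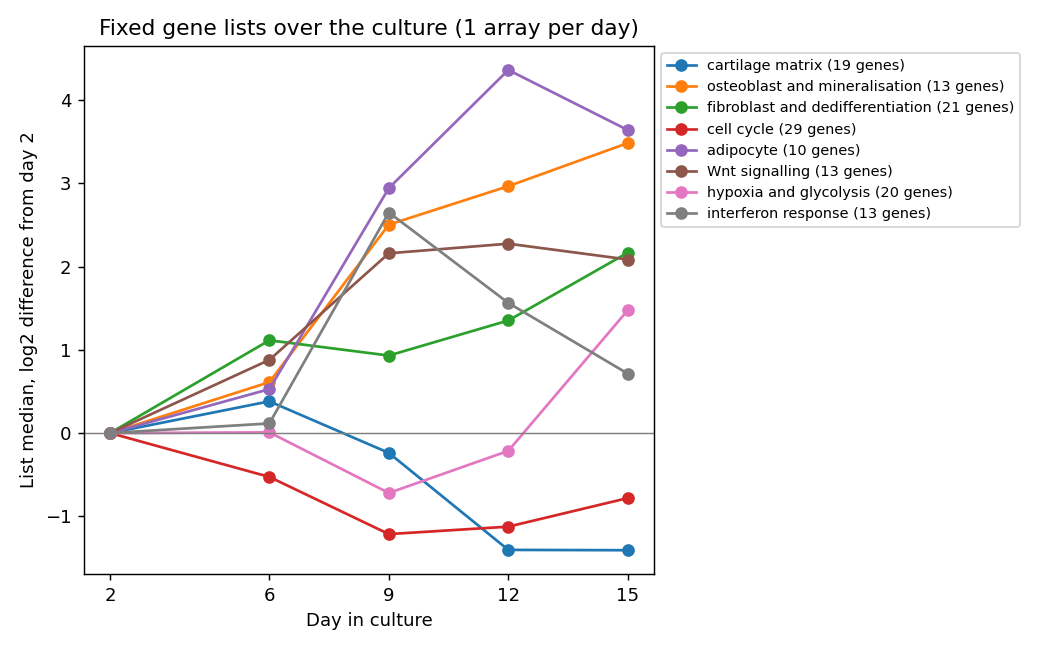
Median log2 difference from day 2 of 8 fixed gene lists against day in culture, 1 array per day. The osteoblast list reached 3.49 at day 15, the adipocyte list was highest at day 12 with 4.36, the interferon list at day 9 with 2.65, and the hypoxia list was at -0.21 on day 12 and 1.48 on day 15.

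Signalling genes differed by pathway. In the Wnt list, 9 of 13 measured members were at least 2-fold higher at day 15 and 0 lower, with a median of 2.09 above all random lists, or 0.60 with no filter, 1.21 against day 6 and 0.48 against day 9. The leading members encode secreted proteins, several of them Wnt antagonists. Dkk3 was at least 49.0-fold higher (16.6-fold by another probe set), Ccn5 at least 35.6-fold, Sfrp2 15.9-fold and Wif1 at least 14.2-fold. In the BMP and TGF-beta list 7 of 20 were higher and 5 lower, with a median of -0.12 at percentile 28.8. The 5 lower members, named after their values were seen, were Bmp6, Smad7, Bmpr1b, Id1 and Id2. The BMP antagonist gene Grem1 was 18.1-fold higher, Chrdl1, another, had 109 at day 2 and 1202 at day 15, the ligand gene Bmp4 was 14.1-fold higher, and Fst, follistatin, 4.72-fold higher. In the hedgehog and PTHrP list 2 of 8 were higher and 0 lower, with a median of 0.76 at percentile 97.3, or 0.23 with the mean over probe sets, 0.09 against day 6 and -0.63 against day 9. Those 2 were the parathyroid hormone receptor gene Pth1r at 12.8-fold and the hedgehog inhibitor gene Hhip at least 4.16-fold, while Gli2 and Kif7 were 1.85-fold and 1.84-fold higher. Adjusted over each list alone, a rising trend was found in 6 Wnt, 4 BMP and TGF-beta and 1 hedgehog member and a falling trend in 3 of the BMP and TGF-beta list, with 0 over all genes tested in these 3 lists.

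Metabolic and stress genes were divided too. Of 20 measured hypoxia and glycolysis genes 12 were at least 2-fold higher at day 15 than at day 2 and 0 lower, with a median of 1.48 above all random lists. Against day 2 the median at day 12 was -0.21, and with days pooled it was 0.69, so the result rests on the day 15 array. Oxidative phosphorylation genes were mostly level, with 21 of 23 within 2-fold and a median of -0.14 at percentile 15.8. The 2 lower members were Cycs, cytochrome c, at 2.39-fold and the citric acid cycle gene Idh3a at 2.20-fold, while Cs and Cox5a were 1.55-fold and 1.51-fold lower. In the unfolded protein response list 15 of 18 were within 2-fold, with a median of -0.15 at percentile 21.4. Pdia4 and Sdf2l1, which act in folding in the endoplasmic reticulum, were 4.95-fold and 2.89-fold higher, and Ddit3, a stress-induced transcription factor gene, 2.26-fold lower. Atf6, a sensor of that response, had 554 at day 2 and 278 at day 15, just under the threshold.

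Of 13 measured interferon response genes 6 were at least 2-fold higher at day 15 and 0 lower, with a median of 0.71 at percentile 96.3, which was 0.01 with the floor at the 60th percentile, 0.04 with no filter and 2.31 with the stricter filter. Gbp2, an interferon-inducible GTPase gene, was at least 8.84-fold higher, Rtp4 5.70-fold, and Bst2 at least 4.95-fold higher, and the RNA sensor gene Ifih1 had 35.2 at day 2 and 183 at day 15. Against day 2 the list median was 2.65 at day 9 and 1.56 at day 12, and from day 9 to day 15 it was -1.95, the opposite sign. Among immediate early and heat shock genes 2 of 15 were at least 2-fold lower at day 15, the chaperone gene Hsph1 at 4.49-fold and the phosphatase gene Dusp1 at 3.80-fold, with a median of -0.37 at percentile 8.33, -0.05 with days pooled and -0.99 against day 9. In the inflammatory list the prostaglandin synthase gene Ptgs2 was 4.41-fold lower and the chemokine gene Cxcl5 2.77-fold higher, and 7 of 9 were within 2-fold. The inflammatory median was -0.14 at percentile 33.4, but 0.16 with days pooled and 0.62 at day 12 against day 2. In the housekeeping list 7 of 10 were within 2-fold, with a median of -0.21 at percentile 17.9. Actb was 1.12-fold lower by its brightest probe set and 2.67-fold higher by another, Tfrc, the transferrin receptor gene, 6.29-fold lower, Polr2a 2.01-fold lower and B2m 2.57-fold higher.

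Markers of other cell types were measured in the same arrays. Adipocyte genes were at least 2-fold higher at day 15 in 8 of 10 measured members and lower in 0, with a median of 3.64 above all 10000 random lists. The median was 2.68 with the floor at the 60th percentile, 2.63 with the mean over probe sets, 1.67 against day 6 and -0.06 against day 9. A rising trend was found in 7 members adjusted over the list alone and in 0 over all genes tested. Besides Fabp4 and Adipoq, the resistin gene Retn was at least 16.9-fold higher and the fatty acid transporter gene Cd36 at least 14.9-fold higher. Smooth muscle and pericyte genes were higher in 5 of 7 members and lower in 1, with a median of 1.24 at percentile 99.7, or 0.61 with no filter, 0.86 against day 6 and 0.37 against day 9. The contractile genes Cnn1, Tagln and Acta2 were at least 12.8-fold, 7.39-fold and 3.27-fold higher (Acta2 1.07-fold by another probe set), and Rgs5 2.36-fold higher. Of the 3 measured osteoclast markers, the acid phosphatase gene Acp5 was at least 4.15-fold higher, Ctsk was higher as above, and Nfatc1 was 2.06-fold lower, with a median of 2.05 at percentile 99.1.

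Few blood, vessel and nerve markers were measured. Among 7 measured macrophage genes 0 were higher and 2 lower, Cd14 by 3.49-fold and Mrc1 by 2.64-fold, with a median of -0.51 at percentile 12.2, or 0.00 with the floor at the 60th percentile and 0.54 against day 9. In the Schwann cell and neuron list 1 of 4 was lower, Cdh19 by 4.62-fold, and the bright members Pmp22 and S100b, with 3683 and 1422 at day 2, were within 2-fold, with a median of 0.08 at percentile 53.5. Of 4 skeletal muscle genes, Tnnt3 was 2.98-fold higher, a difference that turned to -0.08 on the log2 scale with days 12 and 15 pooled against days 2 and 6, and the others were within 2-fold, with a median of 0.37 at percentile 67.8. Both endothelial genes, Eng and Egfl7, were within 2-fold, with a median of -0.06 at percentile 39.5. The lymphocyte list had 1 measured member, Cd8a, at least 2.24-fold higher with only 164 at day 15, at percentile 87.2. The neutrophil list had 1, Camp, with 169 at day 2 and 141 at day 15, at percentile 33.4, and the erythroid list had 0.

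The steps between consecutive days asked when the differences arose. From day 2 to day 6 Ptn was 76.5-fold higher (1.65-fold by another probe set), Aspn 35.2-fold, Bmp4 23.6-fold and Col1a1 22.5-fold higher (8.14-fold by another probe set). In that step Col10a1 was 21.0-fold lower, Ptgs2 15.4-fold, Hbegf 11.9-fold and Phlda2 11.8-fold lower. From day 6 to day 9, Adipoq was 65.2-fold higher, Cd36 26.4-fold (5.11-fold by another probe set) and the proteoglycan gene Srgn 20.9-fold higher. The interferon-inducible GTPase gene Iigp1 was 16.5-fold higher (7.74-fold by another probe set). In that step the glycoprotein hormone gene Stc2 was 13.7-fold lower (3.55-fold by another probe set), Cdsn 11.1-fold, the stress gene Trib3 7.08-fold and Moxd1 6.12-fold lower. From day 9 to day 12, Retn was 5.66-fold higher, Chchd10 5.43-fold (2.27-fold by another probe set), and the apolipoprotein genes Apoc1 and Apoe 4.78-fold and 4.71-fold higher. The immediate early gene Fos was 10.3-fold lower, Scin 4.61-fold, Usp18 4.59-fold and Ifit1 4.30-fold lower.

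From day 12 to day 15 the largest differences among higher genes were in genes induced by low oxygen. Ndufa4l2 was 31.9-fold higher at day 15, the oxygen sensor gene Egln3 15.7-fold (7.92-fold by another probe set), the lactate transporter gene Slc16a3 14.2-fold and Ankrd37 14.2-fold higher. In the hypoxia and glycolysis list all 20 measured members were higher at day 15 than at day 12, 19 of them at least 2-fold, with a median of 1.64 above all 10000 random lists. Bnip3, a mitochondrial autophagy gene, had 3724 at day 12 and 22077 at day 15. The anion transporter gene Slc26a7 was 18.7-fold lower at day 15 than at day 12, Thrsp, a lipogenesis gene, 11.3-fold, the aminopeptidase gene Enpep 9.32-fold and Sult1a1 8.89-fold lower. All 10 adipocyte members were lower at day 15 than at day 12, with a median of -1.09 below all random lists.

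The number of genes that differed at least 2-fold was 1760 from day 2 to day 6, 1100 from day 6 to day 9, 358 from day 9 to day 12 and 903 from day 12 to day 15. The step from day 6 to day 9, in which the adipocyte list median was 1.81, the interferon list median 2.23 and the osteoblast list median 1.23, coincided with a shift in the poly-A spike-ins, control RNAs added before labelling. Their mean log2 intensity was 8.69, 8.73, 9.34, 9.27 and 9.32 in order of day. Relative to the hybridisation spike-ins it was -3.99, -3.49, -3.40, -3.41 and -3.43, which puts the larger shift between days 2 and 6. With a filter at the 70th percentile the 4 counts were 1002, 508, 106 and 378.

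**Figure D3:**
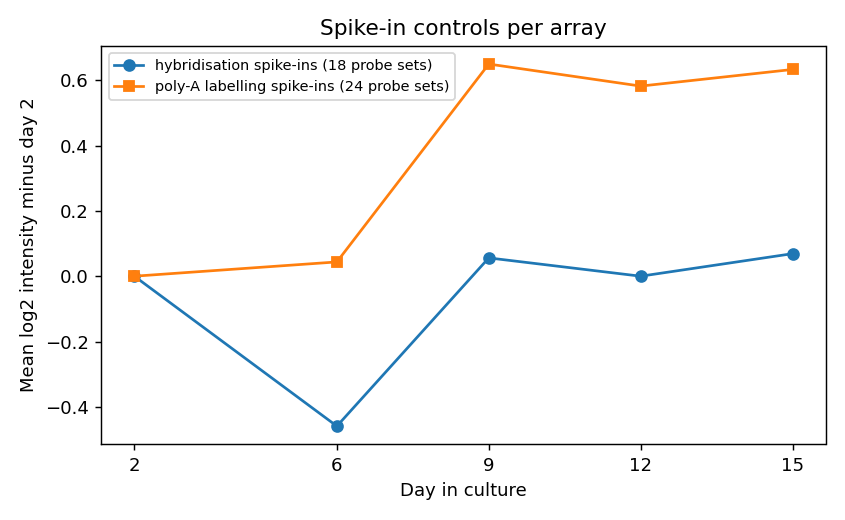
Mean log2 intensity of the spike-in controls on each array minus the day 2 array, against day in culture, for 18 hybridisation and 24 poly-A labelling probe sets. The hybridisation controls were lowest on day 6, and the poly-A controls were higher from day 9 on, with 9.34 at day 9 against 8.73 at day 6. The gap between the 2 kinds of control shifted by 0.50 from day 2 to day 6 and by 0.09 from day 6 to day 9.

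**Figure D4:**
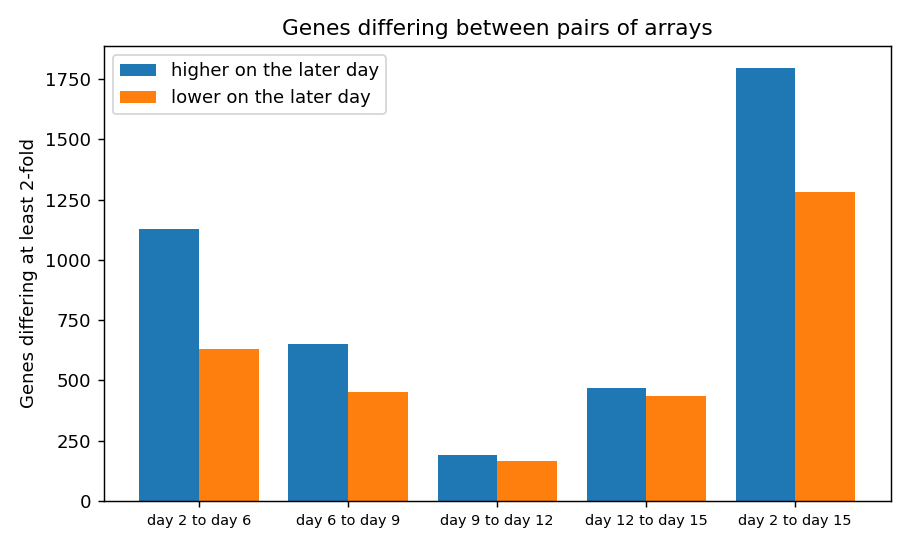
Number of genes (of 11075) at least 2-fold higher or lower on the later of 2 days, for each step between consecutive days and for day 2 to day 15. The step from day 9 to day 12 had the fewest, 191 higher and 167 lower, and day 2 to day 15 had 1798 and 1283.

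Some genes peaked or dipped on a middle day. Slc26a7 was highest at day 12 with 6362, 18.7-fold above the higher of days 2 and 15. Fos, Egr2, Egr3 and Rtp4, 3 growth factor response genes and an interferon-inducible gene, were highest at day 9 and stood 15.0-fold, 12.3-fold, 6.18-fold and 6.54-fold above the higher end. Cytl1, a cytokine-like gene of cartilage, was highest at day 6 with 3510, 7.47-fold above the higher end. The deepest troughs were in Nudt6 at day 6 with 111 (no trough in another probe set), Stc2 at day 9 with 75.8, Evi2a at day 6 with 132, Car6 at day 12 with 117, Anxa8 at day 9 with 301 and the adenylate kinase gene Ak4 at day 9 with 218. In all, 395 genes stood at least 2-fold above both ends on a middle day, 93 of them at day 6, 125 at day 9 and 177 at day 12, and 327 stood at least 2-fold below both.

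The linear trend over the 5 days asked which genes moved steadily. It rose in 6 genes and fell in 0 at an adjusted p under 0.05. Mfap5, a microfibril glycoprotein gene, rose by 0.44 ± 0.03 log2 units per day (SE, limma adjusted p = 0.0350, 5 arrays). Itgbl1, an integrin-like gene, rose by 0.39 ± 0.03, Cd200, a membrane glycoprotein gene, by 0.37 ± 0.03 and Rgcc, a cell cycle regulator gene, by 0.34 ± 0.02, all with the same adjusted p. Mmp13 rose by 0.38 ± 0.03 and Gpx3, the secreted glutathione peroxidase gene, by 0.30 ± 0.02, both with an adjusted p of 0.0399. Mfap5, Itgbl1 and Cd200 were at the floor on day 2, so their slopes and SEs rest on that floor, and with the floor at the 60th percentile 3 of the 6 genes kept an adjusted p under 0.05. All 6 had a higher intensity on each later day than on the day before. The lowest adjusted p of a falling gene was 0.0651, shared by 12 genes, Sim2, Arhgef26, Sox11, Fen1 and Meltf among them, whose slopes ran from -0.34 to -0.15 log2 units per day. At an unadjusted p under 0.05, 1590 genes had a rising and 1410 a falling slope, 3000 in all, and wrong orders of the days gave from 46 to 2637. Leaving out any 1 of the 5 arrays left 0 genes past the adjusted threshold in either direction, and a slope on log2 of the day gave 734 rising and 476 falling.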

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

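The tests of RNA degradation, of labelling between days 2 and 6, of array scaling and gradual build-up for the hypoxia genes, of immune cells and labelling for the interferon genes, and the remarks on the dishes of days 9 and 15 were chosen after the values had been seen. Control probe sets and probe sets without a gene name, which enter none of the comparisons, also carried signal. The poly-A labelling spike-ins were higher by 0.60 on the log2 scale on days 9, 12 and 15 than on days 2 and 6, 19 of 24 probe sets without overlap, while the hybridisation spike-ins, added after labelling, differed by 0.27 and were lowest on day 6 in 18 of 18 probe sets. Of 10092 probe sets with no single annotated gene, 2718 passed the intensity filter, and 415 were at least 2-fold higher and 288 at least 2-fold lower at day 15 than at day 2.

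The spike-in shift raises the question whether genes that differed between day 2 and day 15 reflect a labelling batch between days 6 and 9, or between days 2 and 6, where the shift relative to the hybridisation controls was 0.50 with 1 array at day 2. The differences from day 2 to day 6 and from day 9 to day 15 share no array. Across 11075 genes they had a Pearson r of -0.0718 (bootstrap over genes -0.0980 to -0.0470). Genes are not independent replicates and each difference rests on 1 pair of arrays, so the interval leaves out variation between arrays. The Pearson r lay outside the range set for a batch and below that set against one. The Spearman coefficient, -0.0412, lay inside the range set for a batch, so the test left the batch between days 6 and 9 open. A batch at either place cannot account for the 1003 genes that differed 2-fold between days 9 and 15, but among the 1760 genes that differed between days 2 and 6 and the 1100 between days 6 and 9, those that kept their level later cannot be assigned to batch or time. Unequal RNA degradation is argued against by the Actb 3'-to-5' ratio, which differed 1.08-fold between the arrays of days 2 and 15. Time in culture remains open as the biological explanation.

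Hypoxia and glycolysis genes stood apart on the day 15 array, with a median 1.64 above day 12. Array scaling is argued against, since the list median was 1.62 after quantile normalization and 1.73 with arrays centred on the median. The list as a whole did not build up gradually with days in culture. Its median against day 2 was -0.72 at day 9, with 14 of 20 members lower, and -0.21 at day 12. These values are part of the flagged pattern and not a separate test. Adjusted over the list alone, 2 members, Adm and Pfkfb3, had a rising trend and 0 a falling one. Adm was 3.52-fold, 6.20-fold and 6.06-fold above day 2 at days 6, 9 and 12, so a build-up in some members stays open. The state of the dish or dishes harvested at day 15 stays open. With 1 array at that day, a low oxygen supply before harvest and a late stage of the culture may each give this pattern and cannot be told apart.

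Interferon response genes were highest at day 9 in 12 of 13 measured members, with a list median of 2.65 above day 2. That median was 2.01 with the floor at the 60th percentile, 2.16 with the pseudocount and 3.45 with the filter at the 70th percentile. On day 2, 6 of the 13 were at the floor. Immune cells in the dish remain open: the macrophage list median at day 9 was -0.97 against day 2, but its 7 measured members were dim, with a median intensity of 210 at day 2. A labelling batch between days 6 and 9 would last, so it cannot alone give this course. From day 9 to day 15 the list median was -1.95, with 13 of 13 members lower. The genes were flagged for their peak at day 9, so this fall was part of the pattern and not a separate test. A batch share in the rise from day 6 to day 9 stays open. The state of the dish or dishes harvested at day 9 may account for the peak and cannot be told apart from the time point, with 1 array at that day.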

How the results depend on the processing

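Day 15 against days 6 and 9, day 12 against day 2, the step term and the trend over days 9 to 15 were chosen after the data had been examined; the cause of the differences below was not tested unless stated. Across 158 named genes and 6 processing settings, 806 of 948 values moved by less than 1 SD between probe sets, 142 by more, and 0 of those at least 2-fold apart changed sign. Pooling days 12 and 15 against days 2 and 6 reversed Tnnt3 (-0.0793) and Stc2 (-0.82), and moved the cartilage median to -1.60, the hypertrophic to 1.94 and the osteoblast to 3.73, with 1091 genes higher and 622 lower. Centring on array medians shifted the median of all genes by -0.09 and the share of higher among 2-fold genes from 58.4% to 51.4%. The filter at the 70th percentile, which tests fewer genes, gave 1159 higher, 783 lower and a hypertrophic median of 3.0. The hypertrophic median was 1.83 with the mean over probe sets and 1.93 without a filter. The osteoblast median was 3.70 and 2.63 with the floor at the 20th and 60th percentiles, 2.93 with the pseudocount and 2.97 with the mean over probe sets or without a filter. Day 15 against day 6 gave 932 higher and 682 lower genes and medians of 1.51 (hypertrophic), 2.11 (osteoblast) and -0.46 (cell cycle). Day 15 against day 9 gave 554 higher and 449 lower genes and medians of -1.17 (cartilage), 1.36 (hypertrophic) and 0.98 (osteoblast), and reversed cell cycle (0.20), hedgehog (-0.63), interferon (-1.95), macrophage (0.54) and adipocyte (-0.057). Day 12 against day 2 gave 1.86 (hypertrophic), 2.97 (osteoblast) and -1.13 (cell cycle), and reversed hypoxia (-0.21). Of 121 named genes at least 2-fold apart between days 2 and 15, 15 had the opposite sign from day 6 to day 15, 36 from day 9 to day 15 and 3 from day 2 to day 12; these are given as counts only, a choice made after they were seen. Step counts were, from day 2 to day 6, 1102 with the floor at the 60th percentile and 1002 with the stricter filter. With that floor, the pseudocount and that filter they were 582, 703 and 508 from day 6 to day 9, 144, 182 and 106 from day 9 to day 12, and 510, 558 and 378 from day 12 to day 15. The trend counts were the least stable: 10 rising and 1 falling with centred arrays, 1 falling with the floor at the 20th percentile, 66 and 22 with the pseudocount, 119 and 85 with the stricter filter, 734 and 476 on log2 of the day, 278 and 172 with an intensity trend in the prior. They were 0 rising without a filter, on the rank of the day, with the step term, over days 9 to 15, and on leaving out any 1 array (0 to 0). The 6 rising genes kept an unadjusted p under 0.05 under each of these settings, and 3 of them an adjusted one with the floor at the 60th percentile. No paired analysis was possible because each day has 1 array. Low signal makes bounds of the differences of 594 genes at least 2-fold apart between day 2 and day 15, at the floor on one of these days.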

Other observations

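The test of carried-over fat cells was chosen after its values had been seen. The bounds of the epithelial test were written after the data had been examined, and for the median of the full list. The choice to leave out the genes that had prompted its list came later still. It was made after the median of the full list, which lay past the bound for epithelial cells, had been seen. Fat cell genes had a course of their own. Adipoq, adiponectin, had intensities of 79.3, 79.6, 5191, 16395 and 5924 in order of day, and Fabp4 267, 1680, 17222, 36538 and 24981. Of 10 measured adipocyte genes 9 were highest at day 12, where the list median against day 2 was 4.36, and the lipoprotein gene Apoe went from 1008 at day 9 to 4749 at day 12. At day 9 the immediate early genes Fos, Egr2 and Egr3 were at 7631, 1633 and 3930, against 739, 496 and 1464 at day 12, on the same array as the interferon response genes Rtp4 (3563) and Ifit1 (930, with the floor or less on days 2, 6 and 15).

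Among 9888 genes above the floor on all 5 days, 416 were higher and 491 lower on each later day, together 9.17%, where other orders of the days gave up to 6.18%. For the linear trend, 1 of 100 orders of the day labels, the true one, gave as many as 6 genes. The highest of the others gave 2. That met the bound set beforehand against a random assignment of the days, but so small a count cannot exclude it. The exact reverse, which has other gaps between the days, gave 0, as did the rank of the day. Leaving out any 1 array also gave 0, with fewer residual degrees of freedom, though all 6 genes kept an unadjusted limma p under 0.05. At that unadjusted threshold the true order gave 3000 genes and the other orders up to 2637. The Gapdh control probe sets had a mean intensity of 43504, 27780, 21040, 22022 and 44535 in order of day.

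Mature fat cells carried over from the rib cage are a candidate source of the adipocyte genes at days 9 to 15. However, 8 of 10 measured members had their lowest value at day 2. This is part of the pattern itself and not separate support, and it argues only against cells that were already mature at day 2. Epithelial cells among the isolated cells at day 2 may account for the kallikrein, keratin and plakophilin genes high at that day. A list of 24 epithelial genes, written after those genes were seen and before it was tested, had 8 measured members with a median of -1.75 at day 15 against day 2, a test that partly repeats the observation behind it. Leaving out Krt18 and Itga6, which had prompted it, the other 6 had a median of -0.95, between the bounds that had been written for the full list. Of these, 4 were lower, 3 of them at least 2-fold: Pkp1 went from 535 to 75.8, Perp from 1552 to 293, Krt8 from 220 to 102 and Krt5 from 165 to 95.4. Epcam had 233 and 307, and Trp63 93.6 and 267, with probe sets from -0.63 to 1.51 on the log2 scale. The question stays open.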
